A study of Mus musculus with 4 samples.

How the data were processed

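Total RNA from 4 cultures of mouse E14.1 embryonic stem (ES) cells was converted to biotin-labelled cRNA and hybridised to 1 Affymetrix array each. Per the labels, the cells were either heterozygous for Sall4 (flox/-, line HET18) or null for it (delta/-, line KO1), and each line was grown on gelatin without feeder cells and on mouse embryonic fibroblast feeders. All cultures received leukaemia inhibitory factor (LIF) and blasticidin, and carried a blasticidin-resistance gene targeted to the Oct3/4 locus, so that cells expressing Oct3/4 were selected. The 2 genotypes and 2 feeder conditions gave 4 groups with 1 array per group. The number of arrays limits the precision of every value.

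The deposited values were used as the authors gave them: linear MAS5 signals (array intensity) for 45101 probe sets, with no detection calls. Per the submitters' processing notes the signals came from MAS5, without a version. The 2% trimmed mean was 100 on each array, so no further scaling was applied. A total of 64 control probe sets were left out. In the table pairing probe sets with genes, 34945 probe sets had 1 symbol, 932 had several and 9160 were not listed. Probe sets with several symbols or none were not used in the main tests. The remaining probe sets named 18193 genes.

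Signals were transformed as log2(signal + 4.6), where 4.6 was the 25th percentile of all signals, and each gene was read by its probe set with the highest mean log2 signal. Genes with a mean log2 value under the 40th percentile of all probe sets (log2 3.81, a signal of 9.46) were left out, and 12485 genes were tested. All folds and log2 differences carry this offset, which draws the folds of weak signals towards 1.

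The model was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) with a genotype term and a feeder term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The additive model left 1 residual degree of freedom per gene, to which eBayes added 4.75 prior degrees of freedom. That residual is the difference between the genotype effects in the 2 feeder conditions, so the test asks whether an effect is large beside that difference. Standard errors (SE) are from this fit. Each genotype was represented by 1 clonal line, so a difference between the lines cannot be told apart from a difference between genotypes.

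A size rule with no test stood beside the model: a gene counted when it differed at least 2-fold with the same sign in both conditions of the other factor, with the brighter array of each pair above the median signal of 17.1. Pairs of single arrays and the interaction of genotype with feeders were treated as values with no test. Differences between genotypes are given as the array labelled null minus the heterozygous array.

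Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. With 1 residual degree of freedom, that correlation is poorly estimated, and that test itself rests on 1 degree of freedom. It could hardly call any list. Fibroblast markers by feeders, of which 34 of 38 rose over all genes, had a camera adjusted p of 3.22e-37 at the preset correlation and 0.752 with an estimated one. At the preset correlation the p-value rests on the spread across genes. With 1 array per group it does not measure how far replicate cultures would differ. Of 30 lists, 29 had enough tested genes, all but the two-cell-stage list. The 30 were the Sall family, core pluripotency, trophectoderm, endoderm, primed epiblast, primitive streak and mesoderm, neuroectoderm, embryonic fibroblast, macrophage and blood, germ cell, two-cell-stage, imprinted, NuRD complex, DNA methylation and polycomb, p53 target, cell cycle, cell cycle inhibitor, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and amino acid stress, heat shock, interferon, LIF target, BMP target, Nodal target, Wnt target, FGF target, Hox, epithelial junction and housekeeping lists. The median of each list was also placed among the medians of 10000 random lists matched on mean expression in 20 bins. Members of a list were tested "adjusted over the list alone" as well as over all genes.

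Named genes followed a rule: Sall4 and Pou5f1; the 10 highest and 10 lowest genes between genotypes and the 8 highest and 8 lowest by feeders, first those past the adjusted threshold and then those ranked by the size rule; the 6 largest positive and negative interactions; and from each list up to 4 members with the largest fitted difference, or up to 12 for the pluripotency and trophectoderm lists. The model, thresholds, lists, naming rule and most alternatives were fixed before the data were examined. A list of 24 immediate-early genes and 4 alternatives that leave out genes were added afterwards.

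The model was tested on simulated data with 12485 genes, 200 of them changed, in 20 runs per size of change. It recovered 9.43% of changed genes at a log2 change of 1, 80.8% at 2 and 93.9% at 3, with 13.6%, 7.05% and 10.9% of calls false. Camera called a shift of -0.5 in the pluripotency list in 20 of 20 runs and 0 of 500 unchanged lists. The simulated genes varied independently of each other, so these counts do not give a rate of false calls for lists of genes that vary together.

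Alternatives covered the normalization between arrays, the offset, the filter, the choice of probe set, the variance trend, a model with 1 factor, leaving out each array, the size threshold, the camera correlation and leaving out genes higher on feeders. Gene neighbours were taken from the RefSeq annotation of GRCm38.p6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.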

Results

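The data were array signals from 4 cultures of mouse ES cells, 1 array for each combination of Sall4 genotype (heterozygous or labelled null) and feeders (absent or present). The median signal was 16.1 on the heterozygous array and 17 on the array labelled null without feeders, and 17.1 and 18 on the corresponding arrays with feeders. The ratio of 3' to 5' actin probe sets lay between 1.22 and 1.29. Spearman correlations between arrays, taken across probe sets, ran from 0.911 to 0.941, with 0.931 for the pair without feeders and 0.941 for the pair on feeders. There were no replicate arrays, so no spread within a group was measured.

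Sall4, the zinc finger transcription factor named in the genotype, gave a higher signal on the arrays labelled null. The brighter of its 2 probe sets read 1126.5 in heterozygous cells and 1670.5 in cells labelled null without feeders, and 780.8 and 1452.4 on feeders. The fitted log2 difference of this probe set was 0.73 (SE 0.12, adjusted p = 0.152 over all genes). The other Sall4 probe set was 2.54-fold higher without feeders and 2.40-fold higher on feeders. The labels state neither which part of the gene was deleted nor where these probe sets lie, so it was not known whether these signals check the genotype, and the direction of every genotype difference rests on the labels. Pou5f1, which encodes Oct3/4 and was under selection in all cultures, had signals of 1284, 977, 1112 and 1187 in heterozygous cells without feeders, labelled-null cells without feeders, and the same genotypes on feeders. Its fitted log2 difference was -0.15 (SE 0.14, adjusted p = 0.721).

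The first comparison asked how ES cells labelled Sall4-null differed from heterozygous cells in both feeder conditions. Rhox5, a homeobox gene of a reproductive gene cluster, fell from a signal of 2229 to 118 without feeders and from 2660 to 247 on feeders. Fmr1nb, a cancer/testis gene, fell from 369 to 27.4 and from 382 to 32.3, and the calmodulin-like gene Calml4 fell from 122 to 11 and from 344 to 33.1. AF067061 fell from 421 to 61.5 and from 715 to 87.6. By camera at its preset correlation, genes of naive pluripotency and epithelial junctions were lower as groups on the arrays labelled null. Fibroblast markers, imprinted genes, genes of early neural tissue and Wnt targets were higher by the same test. The camera adjusted p of these lists ran from 8.61e-12 for fibroblast markers to 0.00655, and was 0.773 for each with an estimated correlation. The former values rest on the spread across genes, not between cultures, and the latter on 1 degree of freedom. The median of fibroblast markers was 1.14 without feeders and 0.41 on feeders. Arrays from cultures on feeders carry feeder RNA, and feeder cells left in the culture without feeders stay possible. The rise of these markers therefore cannot be assigned to ES cells.

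Those 4 genes were the ones that changed by the additive limma test. The log2 difference was -3.80 for Rhox5 (SE 0.20, adjusted p = 0.0145), -3.47 for Fmr1nb (SE 0.18, adjusted p = 0.0145), -3.11 for Calml4 (SE 0.20, adjusted p = 0.0212) and -2.83 for AF067061 (SE 0.17, adjusted p = 0.0203), which was read by a probe set marked x_at that can bind several transcripts. No gene rose over all genes (0 by limma), while 724 genes had an unadjusted p under 0.05 in the higher direction and 811 in the lower, 1535 together against 624 expected by chance. Genes are not independent, and a difference between lines or arrays shared by both feeder conditions would also give such an excess. Itm2a, a membrane protein gene, and Tmem156 had log2 differences of 1.29 and 3.19 and an adjusted p of 0.0502 each, and the former was singled out after its values were seen. With quantile normalization or median centring 7 genes changed, 2 higher and 5 lower. No filter, a filter at the 60th percentile, no variance trend or a model with 1 factor gave 0 genes by limma. Leaving out any 1 of the 4 arrays also gave 0, but needed the model with 1 factor, which gave 0 with all arrays, so these runs do not show what an array contributed. In contrast, testing every probe set gave 20 and leaving out genes at least 2-fold higher on feeders gave 99. The rule for leaving out genes uses arrays that enter the residual, so part of the rise to 99 may be by construction.

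By the size rule, without a test, 139 genes differed at least 2-fold in the same direction in both conditions, 41 higher and 98 lower in cells labelled null, against 15 that differed in opposite directions. The higher genes with the largest differences in both conditions included Tmem156, with signals of 5.5 and 83.6 without feeders and 7.0 and 106 on feeders, and Sall3, a relative of Sall4, with 2.4 and 83.2 without feeders and 5.2 and 41.1 on feeders. Lef1, a transcription factor of the Wnt pathway, had signals of 88.2 and 261 without feeders and 20.3 and 288 on feeders. The homeobox gene En2 was 2.95-fold and 3.10-fold higher, and its relative En1 read 4.5 and 20.2 without feeders and 5.4 and 37.2 on feeders. Ntn1, which encodes the axon guidance factor netrin-1, was 3.17-fold and 2.82-fold higher. The peptidase gene Dpp4 was 3.29-fold and 2.66-fold higher, and Ccdc141, Csrnp3 and Fhit completed the named set. On the lower side St8sia1, which encodes a sialyltransferase, was 3.72-fold and 3.55-fold lower, and Zfp352, expressed in the early embryo, read 39.1 and 5.8 without feeders and 55.7 and 9.8 on feeders. Rps6kl1, Igsf23, Ceacam20 and Ubtfl1 also met the rule. Offsets at the median signal and a filter at the 60th percentile lowered the count of 139 to 58 and 78, a 3-fold threshold to 32, and testing every probe set raised it to 238.

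**Figure D1:**
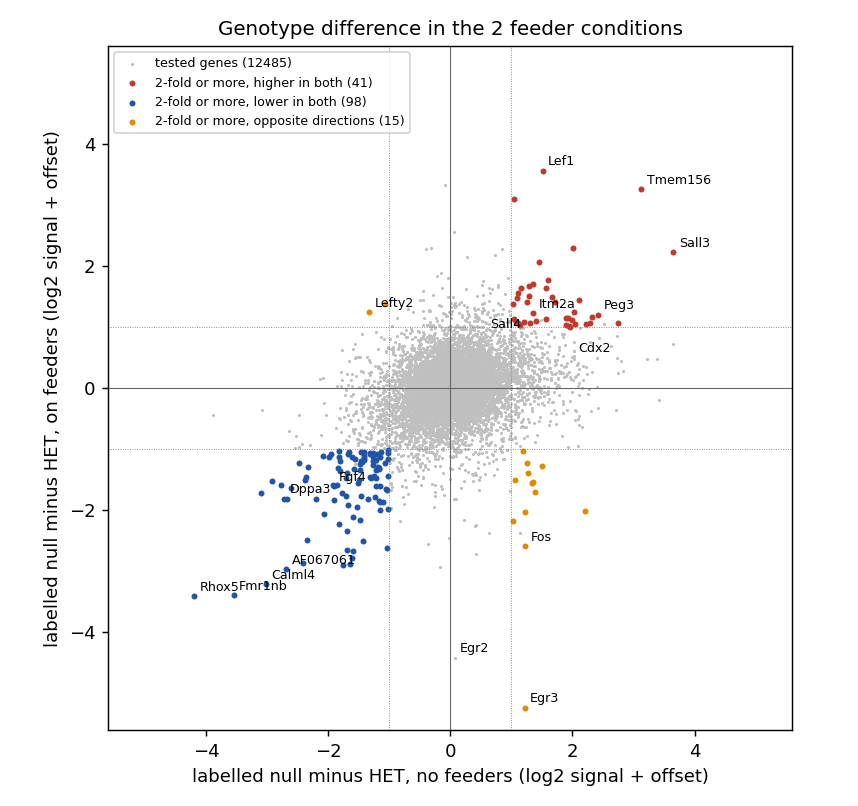
Genotype difference of each tested gene without feeders (x axis) and on feeders (y axis), labelled null minus heterozygous, in log2(signal + 4.6). Each point is 1 of 12485 genes from 1 array per group, coloured points mark the 41 genes higher and 98 lower by at least 2-fold in both conditions and the 15 in opposite directions, and dotted lines mark 2-fold.

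Core pluripotency and naive ES cell genes were lower in cells labelled null, with list medians of -0.40 without feeders and -0.23 on feeders on the log2 scale. Of 28 tested members, 10 fell and 0 rose by limma adjusted over the list alone, and 0 changed over all genes. Dppa3, a maternal factor of the germ line and early embryo, fell by 2.26 on the log2 scale (SE 0.26), and Fgf4, a growth factor secreted by ES cells, fell by 1.76 (SE 0.17). Tcl1, a cofactor of the kinase Akt, fell by 1.04, and the transcription factor gene Tbx3 by 1.03. Utf1, Fbxo15, Klf2, Esrrb, Nanog and Gdf3 fell by 0.69 to 0.47, Nanog from a signal of 1745 to 1232 without feeders and from 2069 to 1394 on feeders. Klf4 had a log2 difference of 0.14 and Pou5f1 of -0.15, and neither passed. Both list medians lay at percentile 0 of random lists. Camera gave an adjusted p of 3.35e-08 at the preset correlation (adjusted p = 0.773 with an estimated correlation).

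**Figure D2:**
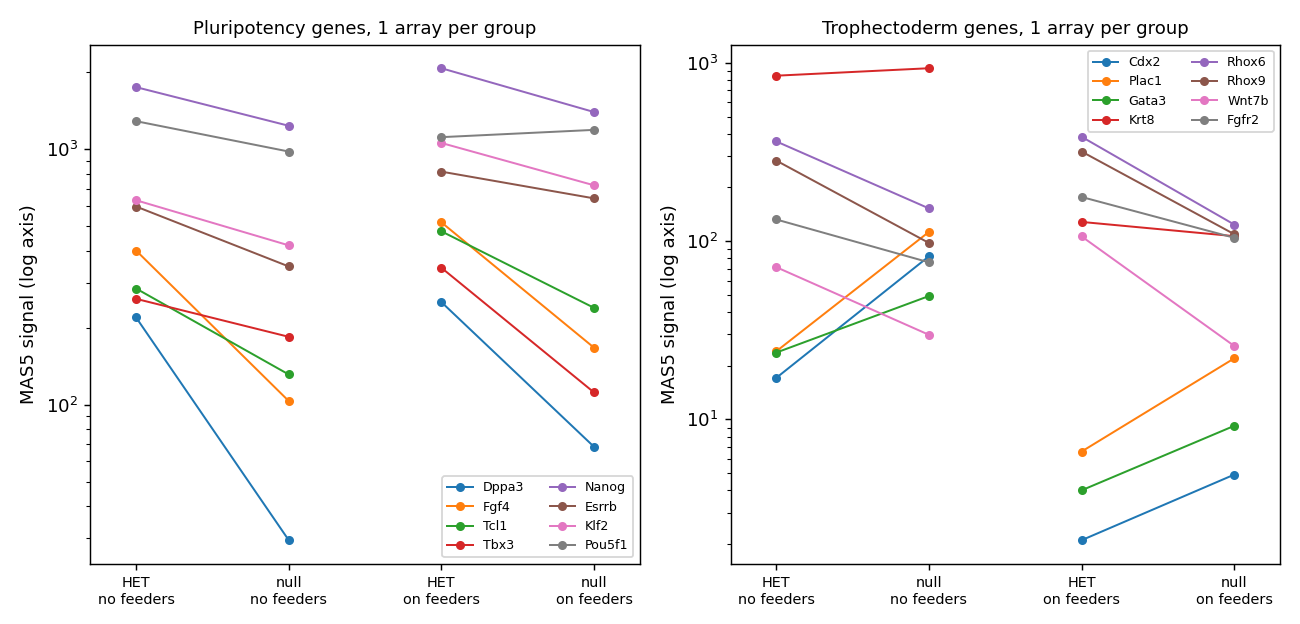
MAS5 signal (log axis) of 8 pluripotency genes and 8 trophectoderm genes on each of the 4 arrays, with lines joining the heterozygous array and the array labelled null within a feeder condition. Dppa3 and Fgf4 are lower on both arrays labelled null, and Pou5f1 stays between 977 and 1284. Plac1 is higher on the arrays labelled null in both conditions. Cdx2 is higher on the array labelled null without feeders, while its signals on feeders, 2.1 and 4.9, lie under the filter signal.

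Trophectoderm genes went both ways. Plac1, a placental gene, rose by 1.64 on the log2 scale (SE 0.30), while Wnt7b and the homeobox genes Rhox9 and Rhox6 fell, as did Plet1 and the receptor gene Fgfr2, all adjusted over the list alone. Without feeders the signals went from 71.4 to 29.8 for Wnt7b, from 283 to 97.6 for Rhox9 and from 362 to 152.5 for Rhox6, and on feeders from 106 to 25.8, 318 to 109 and 385 to 124. Thus 1 of 26 tested members rose, 5 fell and 20 did not pass, and 0 changed over all genes by limma. Cdx2, a transcription factor of trophectoderm, had signals of 17.1 and 82.2 without feeders and of 2.1 and 4.9 on feeders. Its fitted difference of 1.25 (SE 0.45) did not pass. Both Cdx2 signals on feeders lay under the filter signal, so a rise was seen only without feeders. Gata3 read 23.7 and 49.2 without feeders, and the keratin gene Krt8 847 and 933. The list was called lower by camera (adjusted p = 0.00502; adjusted p = 0.774 with an estimated correlation), with a median of -0.59 on feeders but 0.06 without feeders.

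Neuroectoderm genes were higher in cells labelled null, with medians of 0.54 without feeders and 0.69 on feeders. Of 13 tested members 6 rose and 0 fell, adjusted over the list alone, and 0 changed over all genes by limma. Sox1, a transcription factor of the neural plate, rose by 2.06 (SE 0.50), En1 by 1.75 (SE 0.35), Zic1 by 1.55 (SE 0.32) and Sox11 by 1.14 (SE 0.30), followed by Gbx2 and the adhesion gene Ncam1. Among 9 Wnt targets Lef1 rose by 2.54 (SE 0.46), the receptor gene Lgr5 by 1.27 (SE 0.37) and the Wnt antagonist Notum by 0.84 (SE 0.19), adjusted over the list alone, and the medians were 0.75 and 0.29. Axin2 had a log2 difference of 0.60 that did not pass. In the Sall family, a list of 4 genes that includes Sall4 itself, Sall3 and Sall4 rose adjusted over the list alone. Sall1 and Sall2 did not pass. The medians were 0.21 without feeders, where 2 of the 4 were higher, and 0.91 on feeders. The size of the difference depended on the offset where heterozygous signals lay under the filter signal of 9.46, with Sall3 between 1.87 and 4.05 and En1 between 1.03 and 2.48 over their alternatives. Camera gave adjusted p-values of 1.19e-04 for neuroectoderm, 0.00655 for Wnt targets and 0.00456 for the Sall family (adjusted p = 0.773 for each with an estimated correlation). The call for the Sall family was also lost with the filter at the 60th percentile and that for Wnt targets with the mean of probe sets.

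Markers of embryonic fibroblasts, the feeder cell type, were higher on the array labelled null in the culture without feeders. Their list median was 1.14 without feeders and 0.41 on feeders, and 13 of 38 tested members rose adjusted over the list alone, with 0 over all genes by limma. Without feeders the collagen gene Col3a1 read 19.2 in heterozygous cells and 244 in cells labelled null, and Col1a1 1.5 and 36.0, while Col1a2 read 38.4 and 36.2. Lum, which encodes a matrix proteoglycan, rose by 1.52 (SE 0.26) and Twist2 by 1.68 (SE 0.34).

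The imprinted list moved with these markers, at medians of 0.81 without feeders and 0.34 on feeders. Peg3 rose by 1.81 (SE 0.28), with signals of 435 and 2346 without feeders and 276 and 641 on feeders, and Nnat, Rian, Ndn, Cdkn1c, Mest and Meg3 rose by 1.09 to 0.54. The amino acid transporter gene Slc38a4 fell by 1.23 (SE 0.15). In all, 7 of 19 imprinted genes rose and 1 fell adjusted over the list alone. The cell cycle inhibitors had medians of 1.00 without feeders and 0.10 on feeders, with Cdkn2a at 9.9 and 42.9 without feeders, and 0 of 7 passed alone. Hox genes had medians of 0.73 and 0.20, with Hoxd9 at 3.1 and 34.0 without feeders, and 0 of 13 passed. Camera gave adjusted p-values of 8.61e-12 for fibroblast markers, 8.12e-06 for imprinted genes, 0.00456 for inhibitors and 0.00999 for Hox genes (adjusted p = 0.773 for each with an estimated correlation). The lower values rest on the spread across genes and not between cultures. In each of these lists the median was larger in the pair without feeders, 1 array against 1. Without genes at least 2-fold higher on feeders, the Hox call was lost (adjusted p = 0.632, range over its alternatives 0.00143 to 0.773), as it was with a model of 1 factor. The rule for leaving out genes reads the heterozygous array without feeders, which also enters this genotype difference. Part of that loss may thus be by construction.

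Cholesterol synthesis genes were lower in cells labelled null as a list, at medians of -0.79 without feeders and -0.08 on feeders, from 1 pair of arrays each and without a test of the difference. Hmgcs1, an early enzyme of the pathway, read 1945 and 927 without feeders and 1056 and 909 on feeders, and Cyp51 262 and 107 without feeders, but 0 of 17 members passed adjusted over the list alone. In the list of unfolded protein and amino acid stress, with medians of -0.22 and -0.48, the pseudokinase gene Trib3 fell by 1.03 (SE 0.19) and the serine synthesis gene Psat1 by 0.63 (SE 0.12), 2 of 15 members adjusted over the list alone. Of 18 epithelial junction genes 7 fell by the same test: Rab25 by 1.67, the claudin genes Cldn4, Cldn7, Cldn3 and Cldn6 by 0.96 to 0.70, St14 by 0.69, and Cdh1, which encodes E-cadherin, by 0.59 (SE 0.16). Their medians were -0.41 and -0.29. Camera gave adjusted p-values of 1.79e-05 for cholesterol synthesis (adjusted p = 0.774 with an estimated correlation), 0.00129 for stress and 0.00243 for junctions (adjusted p = 0.773 for both with an estimated correlation).

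**Figure D3:**
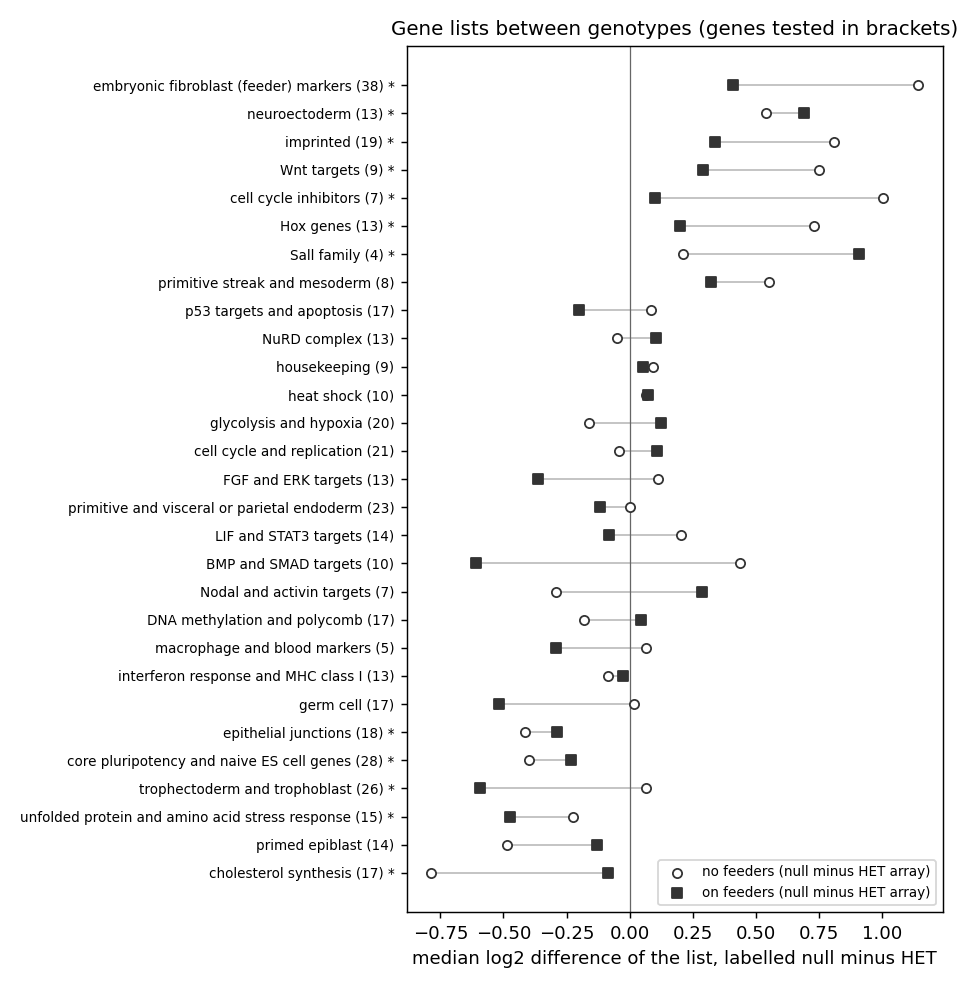
Median log2 difference between the array labelled null and the heterozygous array for 29 gene lists, without feeders (open circles) and on feeders (filled squares), with the number of tested genes in brackets and a star on the 12 lists with a camera adjusted p under 0.05. The fibroblast list reaches 1.14 without feeders, and the trophectoderm list lies at 0.06 without and -0.59 on feeders.

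In all, 12 of 29 lists were called between genotypes at the preset correlation, 7 higher and 5 lower, and 0 with an estimated correlation. The latter test had 1 degree of freedom and could hardly call any list, so its 0 decides nothing. Among the lists not called, genes of the primed epiblast (adjusted p = 0.101) held 1 member that rose, Lef1, and 4 that fell adjusted over the list alone, with Otx2 at -1.52, Car4 at -1.28, Fgf5 at -1.28 and Cldn6 at -0.70. In the germ cell list (adjusted p = 0.101) the meiosis gene Sycp3 fell by 1.06 and the RNA-binding gene Dazl by 1.04, 2 of 17 by the same test. The endoderm list (adjusted p = 0.984) had 3 members that rose, led by Plat at 1.03, and 4 that fell, led by Amn at -1.33, of 23 by the same test. Oas1a fell by 1.18, the 1 of 13 interferon genes to pass (adjusted p = 0.25), Gbx2 rose among LIF targets (adjusted p = 0.836), and Skil rose by 0.43 among Nodal targets (adjusted p = 0.984). No member passed adjusted over the list alone in the lists of primitive streak and mesoderm (adjusted p = 0.101), macrophage and blood (0.836), NuRD complex (0.712), DNA methylation and polycomb (0.172), p53 targets (0.836), cell cycle (0.761), glycolysis and hypoxia (0.712), heat shock (0.211), BMP targets (0.395), FGF targets (0.893) and housekeeping (0.373). For glycolysis and FGF targets the list median was above 0 and the camera direction lower, and for LIF and Nodal targets the median was below 0 and the direction higher. Of the two-cell-stage list, Zfp352 alone of 9 genes was tested, at a log2 difference of -2.07 (SE 0.28, adjusted p = 0.126 over all genes).

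Between single arrays, without a test, 843 genes differed at least 2-fold between genotypes without feeders, 472 higher and 371 lower in cells labelled null, and 429 differed on feeders, 167 higher and 262 lower. Over every probe set the excess of lower ones on feeders was gone, with 496 higher and 481 lower. Under median centring the splits were 414 and 418 without feeders and 126 and 303 on feeders. Without genes at least 2-fold higher on feeders in heterozygous cells, the 472 higher genes became 231 and the 371 lower 360. That rule reads the same heterozygous array without feeders and so removes genes low on it, which fixes part of this shift. Across tested genes the differences in the 2 conditions had a Pearson r of 0.32 and a Spearman rho of 0.28, and genes are not independent replicates. Their standard deviations were 0.550 without feeders and 0.447 on feeders.

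The second comparison asked what the presence of feeders changed. Arrays from cultures on feeders carry RNA of the feeder cells as well as of ES cells, so a difference does not separate the cell types. Fibroblast genes were far higher on feeders: Mgp, an inhibitor of calcification in matrix, rose by 7.10 on the log2 scale (SE 0.39), the matrix gene Postn by 7.08 (SE 0.27) and the collagen cross-linking enzyme Lox by 6.16 (SE 0.37). Lyz1, Bgn, S1pr3, S100a4 and Col1a1 rose by 6.08 to 5.75. Where signals without feeders were near background the size depended on the offset: Lyz1, at 0.8 and 0.4 without feeders, was at 4.36 with an offset at the median signal and 8.44 with no offset, and at 3.11 with the mean of its probe sets. The keratin genes Krt8 and Krt18 fell by 2.88 (SE 0.17, adjusted p = 0.00143) and 2.42 (SE 0.27, adjusted p = 0.00961), Krt8 from a signal of 847 to 128 in heterozygous cells and from 933 to 107 in cells labelled null. Other genes that fell were the neuropeptide gene Nts at -3.12, the interferon-inducible gene Gbp2b at -2.65, the junction protein gene Ajuba at -2.33, Nrk at -2.30, Nnat at -2.21 and the carbonic anhydrase gene Car2 at -2.19.

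By the additive limma test 595 genes changed with feeders, 485 rose and 110 fell, and 2725 had an unadjusted p under 0.05. The size rule held for 560 genes, 494 higher and 66 lower, against 10 in opposite directions, and 456 genes met both. In heterozygous cells 1179 genes differed at least 2-fold (974 higher, 205 lower), and in cells labelled null 1074 (786 higher, 288 lower). The count of 595 depended on the settings: it was 183 without a variance trend and 1561 with every probe set, and 231 with a model of 1 factor. With that model it was 313 without the heterozygous array without feeders, 534 without the array labelled null without feeders, 46 without the heterozygous array on feeders and 23 without the array labelled null on feeders.

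Of 38 fibroblast markers 34 rose over all genes, with medians of 4.43 in heterozygous cells and 3.13 in cells labelled null. Trophectoderm genes were lower on feeders, at medians of -0.25 and -0.78. Of 26 members 7 fell over all genes and 9 adjusted over the list alone, among them Krt8, Krt18, Krt19 at -2.03, Cdx2 at -2.44, Gata3 at -1.84, Plac1 at -1.75 and Id2 at -1.54. In the primed epiblast list Car4 fell by 1.52 and Dusp6, a phosphatase that limits ERK signalling, by 1.08 over all genes, and Pou3f1 fell by 2.18 adjusted over the list alone. The pluripotency list was higher by medians of 0.13 and 0.27, with Klf4 up by 0.91 (SE 0.13) and Klf2 by 0.76 (SE 0.12) over all genes, while the RNA-binding gene Lin28a fell by 1.02 (SE 0.14). Stress genes were higher as a list, with Chac1 up by 2.42, Herpud1 by 1.71, Trib3 by 1.64 and Atf4 by 0.96. Of 15 tested members 5 rose over all genes, and 7 rose and 1 fell, Hspa5 at -0.26, adjusted over the list alone. In the glycolysis and hypoxia list Adm rose by 2.63, the angiogenic factor gene Vegfa by 1.63 and Bnip3 by 1.04, and in the Hox list Hoxb3 rose by 2.75, Hoxc8 by 2.31 and Hoxc6 by 1.61.

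Camera called 12 of 29 lists by feeders. Higher lists were fibroblast markers (adjusted p = 3.22e-37), stress (0.00168), Hox genes (0.00272), glycolysis and hypoxia (0.0371) and pluripotency (0.0451). Lower lists were primed epiblast (8.34e-05), trophectoderm (1.41e-04), cell cycle (0.00588), NuRD complex (0.0126), cholesterol synthesis (0.0292), BMP targets (0.0292) and epithelial junctions (0.0395). With an estimated correlation, a test that could hardly call any list, none of the 29 held (lowest adjusted p = 0.752). With the filter at the 60th percentile 6 held. The pluripotency call was also lost with median centring, the mean of probe sets, no variance trend and 1 factor, the calls for glycolysis and junctions with median centring and no trend, those for cholesterol synthesis, BMP targets and junctions with the mean of probe sets, that for cholesterol synthesis with 1 factor and that for cell cycle with quantile normalization. Cholesterol genes had medians of -0.64 in heterozygous cells and 0.16 in cells labelled null, and BMP targets of 0.14 and -0.72. The adjusted p was 0.144 for the Sall family and for neuroectoderm, where Sox11 fell by 2.17 over all genes, 0.683 for imprinted genes, of which 4 rose and 3 fell over all genes, and 0.0814 for macrophage and blood markers, where Lyz2 rose by 4.14. For the other lists it was 0.572 (endoderm), 0.426 (streak and mesoderm), 0.867 (germ cell), 0.115 (DNA methylation and polycomb), 0.918 (p53 targets), 0.118 (cell cycle inhibitors), 0.416 (heat shock), 0.714 (interferon), 0.683 (LIF targets), 0.211 (Nodal targets), 0.437 (Wnt targets), 0.0516 (FGF targets) and 0.103 (housekeeping).

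The third comparison asked where the genotype difference depended on feeders, as values with no test. Early response genes stood at the top: Egr3 read 11.8 and 33.6 without feeders but 701 and 14.2 on feeders in heterozygous and labelled-null cells, and Egr2 7.2 and 7.8 but 299.5 and 9.7. Ptgs2, which encodes a prostaglandin synthase, read 46.4 and 230 without feeders and 744 and 180.5 on feeders, and Fos 84.3 and 203 against 854 and 138. Their differences of log2 differences, without minus on feeders, were 6.45 for Egr3, 4.48 for Egr2, 4.22 for Ptgs2 and 3.81 for Fos, followed by Tm4sf1 at 3.61 and the growth factor gene Ereg at 3.51. In the opposite direction stood Eif2s3y at -3.44, the cadherin gene Cdh9 at -3.40, Myom2 at -2.72, Glcci1 at -2.67, Adgrv1 at -2.60 and Lefty2, an antagonist of Nodal, at -2.57. In all, 984 genes had an interaction of at least 2-fold, 593 positive and 391 negative, and an offset at the median signal lowered the count to 451, the filter at the 60th percentile to 512, while every probe set gave 2297.

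**Figure D4:**
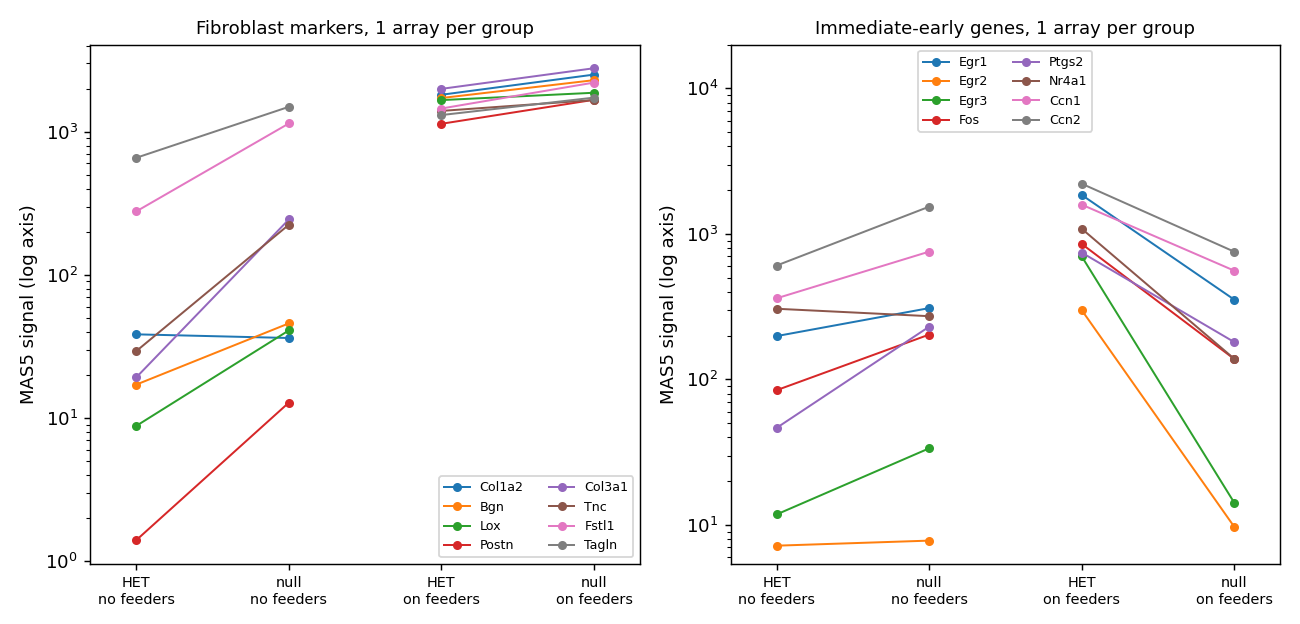
MAS5 signal (log axis) of 8 fibroblast markers and 8 immediate-early genes on each of the 4 arrays, with lines joining the heterozygous array and the array labelled null within a feeder condition. Without feeders Col3a1 differs 19.2 to 244 while Col1a2 reads 38.4 and 36.2, and on feeders Egr3 reads 701 and 14.2.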

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

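The tests on immediate-early genes were chosen after the result was seen, and so was part of their gene list. The genotype difference went in opposite directions in the 2 feeder conditions, by at least 2-fold in each, for 15 genes, and these differences were not tested. The 13 genes higher without feeders and lower on feeders in cells labelled null were C2cd4b, Ccn1, Ccn2, Dusp5, Edn1, Egr3, Errfi1, F3, Fos, Ier5, Phlda1, Ptgs2 and Tuft1, all named after their values were seen. The 2 genes with the opposite pattern were Lefty2, at signals of 427 and 167 without feeders and 186 and 444 on feeders, and Ltb, at 24.9 and 9.5 and at 4 and 17.7. The median of BMP targets was 0.44 without feeders and -0.61 on feeders, and that of Nodal targets was -0.29 and 0.29, in both cases without a test of the difference.

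Of the 13 genes, Ccn1, Ccn2, Dusp5, Egr3, Errfi1, Fos, Ier5, Phlda1 and Ptgs2 were listed as immediate-early genes, which respond within a short time to growth factors or stress. Part of that list was chosen after these results were seen, so this overlap and the values of the list follow in part from the choice. In a list of 24 such genes, 10 of which were also in a list fixed earlier, the median log2 difference was 0.70 without feeders and -1.52 on feeders, 21 were at least 2-fold lower on feeders in cells labelled null, and 20 had their highest signal on the heterozygous array with feeders. A larger amount of feeder RNA on that array was argued against, since the fibroblast list was higher, not lower, on the array labelled null with feeders (median 0.41). Handling of that culture before harvest may have raised these genes, and it cannot be told apart from an effect of genotype, because the group held 1 array. An effect of genotype on the response to feeders stays open and was not tested.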

How the results depend on the processing

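All alternatives were planned except 4, chosen after the data were seen. Leaving out the fibroblast list gave 586 genes changed by feeders. Leaving out immediate-early genes gave 408 genes at least 2-fold apart between genotypes on feeders and 962 interactions, and leaving out genes higher on feeders gave 591 genes without feeders (231 higher, 360 lower). All 4 totals stayed within 1.5 times the reported counts, but in the last the higher genes went from 472 to 231, in part by construction, since the genes left out were picked with the heterozygous array without feeders that also enters that difference. No paired analysis was possible because the labels give no replicate numbers, beyond the comparison within each feeder condition that the model makes. The cause of the other differences given here was not tested unless stated.

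The 4 genes changed between genotypes became 7 with quantile normalization and 7 with median centring (2 higher, 5 lower in each), 20 with every probe set, and 0 by limma with no filter, with the filter at the 60th percentile, without a variance trend and with the model of 1 factor, and 0 to 0 when 1 array was left out in that model. With genes at least 2-fold higher on feeders left out, 99 changed (31 higher, 68 lower), among them 3 of the 4. That rule removed 1002 genes by a difference that enters the residual, and the prior degrees of freedom rose from 4.75 to 6.40. The 595 genes changed by feeders became 393 with no offset, 269 with no filter, 268 with the filter at the 60th percentile, 384 with the mean of probe sets, 1561 with every probe set, 183 without a trend, 231 with 1 factor and 23 to 534 with 1 array left out. Median centring split them as 452 higher and 164 lower.

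The size counts moved with 4 settings. An offset at the median signal gave 58 genes between genotypes in both conditions, 462 without feeders, 211 on feeders and 451 interactions. The filter at the 60th percentile gave 78, 534, 225 and 512, and 354 by feeders, and every probe set gave 238, 1604, 977 (496 higher, 481 lower) and 2297, and 1131 by feeders. A 3-fold threshold gave 32 in both conditions, 240 without feeders, 111 on feeders and 262 by feeders. The correlation of 0.32 across genes was 0.295 with no offset, 0.342 with an offset at the median signal, 0.201 with no filter, 0.353 with the filter at the 60th percentile and 0.268 with every probe set.

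The 12 lists called between genotypes numbered 10 to 13 under the other settings and 0 with an estimated correlation. The 12 called by feeders numbered 8 to 15, except 6 with the filter at the 60th percentile and 0 with an estimated correlation. The test with an estimated correlation had 1 degree of freedom and could hardly call any list. The pluripotency call by feeders (adjusted p = 0.00421 to 0.752 over its alternatives) held under 4 of 10, and that between genotypes (1.13e-08 to 0.773) under 10 of 11. Some signs differed within single pairs: trophectoderm genes were at 0.063 between genotypes in the pair without feeders, BMP targets at 0.14 by feeders in the heterozygous pair and cholesterol genes at 0.16 in the pair labelled null. Calml4 by feeders ran from -0.24 to 2.97 with 1 array left out, at -0.14 without the array labelled null without feeders and -0.24 without the heterozygous array on feeders, since that model takes in the genotype difference. Among the other values for single genes, 6134 stayed on their side of the threshold over all genes, 298 fell short of it and 50 newly passed it. Of the 6134, 374 changed sign while not past the threshold, 332 of them with 1 array left out, where the model with 1 factor mixes in the other factor. Among genes that passed adjusted over the list alone, 16 of 72 between genotypes had the other sign with 1 array left out, namely 10 of 13 fibroblast markers and Meg3, Mest, Nnat, Sox11, Plat and Sparc, and 1 of 126 by feeders, Slc38a4. These runs set arrays of unlike conditions against each other, so such changes carry the effect of the other factor. For lists, 664 values stayed on their side, of which 44 changed sign while not called in either, 46 fell short and 5 newly passed.

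Without detection calls, signals near background were limited by the filter at a signal of 9.46, the offset and, in the size rule, the median signal.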

Other observations

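The tests on fibroblast markers, on Sall4 and on neighbouring genes were chosen after the results were seen, except the repeat without probe sets marked s_at or x_at. Further genes were lower in cells labelled null by the size rule, and those named here were singled out after their values were seen. Pramel7, a gene of early embryos, read 70.6 and 15.3 without feeders and 42.5 and 11.1 on feeders, and its relative Pramel6 28.6 and 6.4, and 50.4 and 4.1. Spesp1, a sperm protein gene, read 54.5 and 17.3 without feeders and 113 and 16.1 on feeders. Gldc, which encodes a subunit of the glycine cleavage system, read 762 and 236, and 837 and 395. None of these passed the adjusted test.

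A share of the 98 genes lower in both conditions lay near another such gene among the tested genes. Of them, 19 had another within 5 tested genes on either side, against a median of 8 in 10000 random draws matched on signal (permutation p = 0.0032, one-sided). They included Rhox5, Rhox6 and Rhox9; Dppa3 and Apobec1; Pramel6 and Pramel7; Igsf23 and Ceacam20; Calml4 and Spesp1; and AF067061 with AF067063. Without genes read by probe sets marked s_at or x_at, which can bind several transcripts, the count was 15 against a random median of 6 (permutation p = 0.018), which argues against such probe sets as the whole source, although AF067061, Pramel6 and Pramel7 were read by them and were not in that count. Neighbouring genes may thus have been lower together, a hypothesis found and tested on the same data, and 1 line per genotype leaves a difference between the lines open.

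Fibroblast markers were higher on the array labelled null without feeders, although no feeders were present per the labels. Of the 38 markers, 21 were above the median signal in heterozygous cells without feeders, 0 were in another of the 30 lists, and Ccn1 and Ccn2 were also among the 24 immediate-early genes. Feeder cells left in that culture may have contributed, but were argued against as the whole source at the same share for all markers. Of the 16 markers less than 16-fold brighter on feeders, 7 (Acta2, Cav1, Ccn1, Ccn2, Fstl1, Pdgfrb and Tagln) rose by more than the upper bound of the median share of the 22 brighter ones, beyond the spread of other genes. So did 5 of 9 with the threshold at 8-fold and 8 of 26 at 32-fold. The threshold and the shares both use the 2 heterozygous arrays, so part of this contrast may be by construction. The binomial p of 5.72e-08 takes all markers to have the same true share and genes to be independent. The shares of the 22 themselves ran from -1.40% to 14.2%, so this p-value does not measure the strength of the evidence. Feeder cells with unequal shares of the markers stay open. Feeder cells at the common share of all markers, 7.19% of the excess on feeders, cannot be told apart from expression in cells labelled null for the brighter ones, since the upper bound of their median share (exact sign test) was 5.52% at 16-fold but 9.08% at 8-fold. A smaller share cannot be told apart either, as 13.6% of the 22 lay outside 0.5 to 2 times their median share of 2.06%, and Col1a2 did not rise, with 38.4 and 36.2 without feeders and 1812 on feeders. Scaling of the arrays was argued against, since the list median was still 1.08 under median centring and 1.11 under quantile normalization, and an effect of genotype stays open and was not tested.

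The Sall4 signal was higher on the arrays labelled null. An exchange of the genotype labels in 1 feeder condition was argued against, since 9.74% of the genes at least 2-fold apart in both conditions went in opposite directions, where an exchange would put most of them there. An exchange in both conditions could give the same values and cannot be told apart from probe sets outside the deleted part: 2 of 2 Sall4 probe sets were higher on the arrays labelled null in both conditions. Such an exchange would turn the direction of every genotype difference.

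The Y-linked gene Eif2s3y read 78.2 in heterozygous cells and 1.0 in cells labelled null without feeders, and 91.8 and 66.4 on feeders. Feeder RNA can enter the arrays on feeders, so these values do not show whether the ES cells on both arrays labelled null were alike. The transcription factor gene Msx2 read 35.3 and 128 without feeders and 39.1 and 24.5 on feeders, and Id1, a target of BMP signalling, 302 and 722.5 without feeders and 155 and 98.2 on feeders. Lefty1, an antagonist of Nodal, read 1271 and 902 without feeders and 661 and 1804 on feeders. These are values of single arrays.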
